A study of Mus musculus with 6 samples.

How the data were processed

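Brg1 CUT&Tag was performed on innate lymphoid cells of group 2 (ILC2s) sorted from mouse lung. In CUT&Tag an antibody directs a transposase to the DNA around its target, so that the sequenced fragments mark where the target was bound. Brg1, encoded by Smarca4, is an ATPase of the BAF chromatin remodelling complex. The labels describe 6 libraries in 3 groups of 2. The first group came from wild-type mice given PBS and the second from wild-type mice given 500 ng of interleukin 33 (IL-33), both over 4 days, and these cells were sorted as lineage-negative CD25+ ST2+. The third group came from IL-33-treated mice whose Il5-expressing cells carried a Smarca4 deletion. It is labelled as an input and negative control, and was sorted by another gate, for CD45 and a red fluorescent reporter. Per the labels' protocols, female mice were used and each biological repeat held 50000 cells pooled from 2 to 6 mice. The libraries were built with a commercial in-situ kit.

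The values analysed were raw counts, 1 whole number per genomic region and library, as deposited by the authors in a table of 123742 regions that do not overlap. Per the submitters' processing notes, the build was mm10 and the tools named are fastp, Bowtie2 2.5.3, MACS2, bedtools 2.31.1, ChIPseeker 1.28.3, deepTools 3.5.4 and edgeR 3.34.0. Their settings, the treatment of duplicate reads, and whether regions were called on single or pooled libraries are not given in the sources used here. How regions were called decides which weak regions were counted at all. The table held the 4 wild-type libraries, and its column names matched the labels of those libraries. The knockout libraries were not analysed here. The 2 planned comparisons against the knockout, their gene lists, the fit of all 3 groups together and the restriction to regions above the knockout signal were therefore not run, and no background was subtracted from any value below.

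Counts over regions summed to 5902278 and 5846606 in the PBS libraries and to 9627512 and 6845415 in the IL-33 libraries. Reads outside these regions were not used here, so the totals are not sequencing depths. Counting error alone did not account for replicate differences: over regions with at least 20 counts, the chi-square statistic per degree of freedom was 2.55 between the PBS replicates and 3.23 between the IL-33 replicates. All 4 libraries were thus kept as separate replicates. Their common biological coefficient of variation was 0.20.

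The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling factors and the filterByExpr filter, which left 101316 regions. The model held the group alone. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested regions, and a region was called at an adjusted p below 0.05. Levels are TMM-scaled CPM, relative to the total over regions, given as the mean ± SD of 2 libraries, and log2 fold changes are given with their standard error (SE). With 2 libraries per group, 2 residual degrees of freedom remain. The test took its spread wholly from all regions (estimated prior degrees of freedom infinite), so a region's own replicates did not set its p-value or SE. The SD of the 2 libraries shows the region's own spread. Counts were simulated with the real means and totals and a spread following its trend over regions, and 200 of 101316 regions were changed. Of these, 23% of 2-fold changes and 60% of 4-fold changes were called in the right direction. In that simulation 3 unchanged regions were called and 4.85% of unchanged regions had an unadjusted p below 0.05. The simulated spread is of the kind the test assumes, so this does not show the rate of false calls in the real data. With so few changed regions the adjusted threshold is stricter than in the real comparison, so the shares of changed regions called do not carry over to it.

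Each region was assigned to the gene whose span it overlapped or lay nearest to, among 21907 protein-coding and constant-region genes of the GRCm38.p6 gene table, the assembly named mm10 by the submitters. Where spans overlapped, the gene with the nearer end was taken, and 2.16% of regions overlapped at least 2 spans. The gene table used here carried no strand or exons, so regions are described as at a gene end (within 1 kb of either end of a gene span), inside a gene or intergenic. This replaced a planned promoter class, and whether a region is exonic, intronic or in a UTR is not given. Gene ends held 16.8% of regions, against 8.46% and 8.51% after moving all regions by 200000 bp in either direction. Of all regions, 19.6% lay more than 10 kb and 7.31% more than 50 kb outside the assigned gene. An assignment is a position and does not show that a region acts on that gene. Coordinates are printed as the deposited table gives them. The table does not state whether starts count from 0 or 1.

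The test, most alternatives for regions, 16 gene lists and the rule for named regions were fixed before the data were examined. Thinning and several alternatives for gene lists and region classes were added later, as the closing section states. The rule took the 12 regions higher and the 12 lower with the smallest p whose libraries did not overlap between groups, at most 1 per gene. It also took 24 genes of ILC2 biology, each by its region with the smallest p, and up to 4 members of each list by the same measure, giving 104 different regions. A gene's named region is thus its most clearly changed one and does not stand for the gene's other regions, whose counts are given for many genes of the lists but not for every gene named. Many further genes of the fixed lists are given only by counts of their called regions. They were picked after their values were seen. The lists covered ILC2 effectors, ILC2 identity factors, receptors, NF-kB and AP-1 signalling, negative regulators, quiescence and migration, proliferation, metabolism, BAF subunits and housekeeping genes. The other 6 held markers of T cells, of other innate lymphocytes, of B cells, of myeloid cells, of mast cells, basophils and eosinophils, and of lung structural cells. All 361 list genes were matched in the gene table. Lists were tested on log2 CPM (prior count 2) with camera of limma 3.58.1, which compares a list's regions with all other tested regions. A preset correlation of 0.01 and an estimated correlation were used, and p-values were adjusted over the 16 lists. With the estimate, camera rests on the 2 residual degrees of freedom, so few lists can pass. Regions of 1 gene are not independent, and a gene with many regions weighs more than a gene with few.

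Gene ends were compared between higher and lower calls with Fisher's exact test. Alternatives were the Wald test of DESeq2 1.42.0, total-count and RLE scaling, limma on cyclic-loess normalized log2 CPM, the edgeR likelihood ratio test, other filters and thresholds, a replicate block and leaving out each library. Further steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.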

Results

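The study asked how Brg1 occupancy of chromatin in lung ILC2s differs between naive mice and mice given IL-33, an epithelial alarmin that activates these cells through the receptor ST2. Counts of Brg1 CUT&Tag reads over genomic regions were analysed for 2 libraries from PBS-treated and 2 from IL-33-treated wild-type mice, each from a separate pool of animals. Totals over the counted regions were 5902278 and 5846606 in the PBS libraries and 9627512 and 6845415 in the IL-33 libraries. Across regions, log2 CPM correlated at a Pearson r of 0.90 between PBS replicates and 0.91 between IL-33 replicates, and at 0.81 to 0.82 between libraries of different groups. Regions are not independent replicates, so these coefficients describe the libraries only. All values below are for n = 2 libraries per group.

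IL-33 was accompanied by changes of Brg1 signal in both directions. Of 101316 tested regions, 6951 were higher and 9735 were lower after IL-33 (edgeR quasi-likelihood test, adjusted p below 0.05). The higher regions changed by a median of 2.68-fold (interquartile range 1.99 to 3.83) and the lower regions by a median of 1.85-fold (1.54 to 2.55). At least 4-fold differences were seen in 1565 higher and 839 lower regions. Called regions were assigned to 3033 genes with a higher region and 4424 genes with a lower region, 934 of which had both. The balance of directions depended on the scaling. With TMM factors 41.7% of calls were higher, whereas with total counts 8564 regions were higher and 7350 lower (53.8% higher), and the median of all regions moved from 0.04 to 0.15 on the log2 scale. Among calls that also changed at least 2-fold, 5180 were higher and 4114 lower (55.7% higher). The count of 16686 calls fell to 9676 with DESeq2 and to 10920 without PBS replicate 2. Higher calls numbered 4408 without IL-33 replicate 1, and lower calls 6418 without PBS replicate 1 and 5835 without PBS replicate 2.

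Lower regions lay at gene ends more often than higher regions did. Of the 19453 tested regions within 1 kb of a gene end, 2932 (15.1%) were lower and 652 (3.35%) were higher. Inside genes the calls were nearly balanced, with 3881 lower and 3812 higher among 49183 regions. The 32680 intergenic regions held 2922 lower and 2487 higher calls. Gene ends thus made up 30.1% of lower and 9.38% of higher calls (odds ratio 4.16, two-sided Fisher's exact test p = 1.44e-245, which treats neighbouring regions as independent and is therefore too small). Gene-end regions were also the stronger ones, with a median of 9.02 CPM against 4.01 CPM inside genes and 3.86 CPM between them. The odds ratio was 1.85 under cyclic-loess normalization, which removes a trend of the fold change with abundance, and 1.72 among calls of at least 2-fold.

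The most clearly higher region lay inside Itpr1, which encodes a calcium release channel of the endoplasmic reticulum (chromosome 6, 108336889 to 108341486). It rose from 16.2 ± 1.42 CPM to 167 ± 11.96 CPM, a log2 fold change of 3.36 ± 0.13 (SE). A region 17.8 kb from Il10, the gene of an immunoregulatory cytokine (chromosome 1, 130995339 to 131002021), rose from 14.2 ± 3.31 to 114 ± 10.4 CPM (log2 fold change 3.01 ± 0.14). At the end of Tnfrsf8, which encodes the TNF-receptor family member CD30 (chromosome 4, 145310315 to 145315579), signal rose from 18.6 ± 4.79 to 132 ± 14.4 CPM. Regions inside Pik3ca, the gene of a phosphoinositide kinase subunit (log2 fold change 3.67 ± 0.22), and Cdk6, the gene of a cell cycle kinase (2.09 ± 0.12), also rose. So did regions inside Prkag2, a regulatory subunit gene of AMP-activated kinase (2.41 ± 0.13), and Trerf1 (2.82 ± 0.17), and at the end of Dusp2, a phosphatase gene of the MAP kinase pathway (2.28 ± 0.14). The remaining 4 of the 12 lay between genes, nearest to Gtsf1l, Tprg, Pabpc2 and Jarid2 at distances of 29.7 to 409 kb. The steepest of these, near Tprg, rose from 2.45 ± 0.168 to 64.5 ± 7.56 CPM (26.2-fold).

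Among lower regions, the smallest p belonged to a region inside Mmp2, the gene of a gelatinase (chromosome 8, 92843424 to 92850531). Its signal fell from 108 ± 3.44 to 27.0 ± 3.10 CPM (log2 fold change -2.01 ± 0.13). A region inside Gcnt1, a gene of O-glycan branching (chromosome 19, 17334257 to 17343245), fell from 196 ± 2.82 to 67.8 ± 4.51 CPM. Regions inside Niban1 (-2.18 ± 0.15) and Umad1 (-2.27 ± 0.15) fell as well. The others of the 12 were intergenic, the nearest genes being Rarg, a retinoic acid receptor gene (-1.91 ± 0.13), Ywhab, Gm38457, Tmem64, Fam50b, Fgf6, Stt3b and Slc38a6. The largest fall among them was 6.47-fold, at the region 18.2 kb from Fgf6.

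Regions of ILC2 effector genes moved in both directions, 41 of 234 rising and 29 falling (45 and 36 adjusted over the list alone). Under cyclic loess 48 of these regions rose and 22 fell. As a list they did not differ from other regions (camera adjusted p = 0.594, and 0.477 with an estimated correlation). The type 2 cytokine locus on chromosome 11 rose: of 46 tested regions from Il4 through Il13 and Rad50 to Il5 and 20 kb on either side, 20 were higher and 0 were lower at the edgeR threshold. This window was not part of the plan fixed beforehand. By assigned gene, 2 of 5 regions of Il4, 2 of 6 of Il13 and 4 of 15 of Il5 were higher. The other higher regions of the window were assigned to other genes. A region 2.67 kb from Il5, the gene of the eosinophil growth factor interleukin 5 (chromosome 11, 53710021 to 53718127), rose from 68.9 ± 1.69 to 139 ± 5.57 CPM (log2 fold change 1.01 ± 0.11). A region 2.44 kb from Il13 rose from 59.4 ± 1.21 to 111 ± 11.4 CPM (0.90 ± 0.11). The change next to Il4 was smaller (0.66 ± 0.16), and its call ended without PBS replicate 1 (0.46). Regions of Il10 (11 of 14), Il6 (8 of 23), Lif (5 of 17), Osm (3 of 5) and Ccl5 (3 of 12) also rose, and none of theirs fell. The Il6 region with the smallest p, 72.7 kb from the gene, rose from 6.43 ± 0.279 to 54.7 ± 4.15 CPM. Of the 8 higher Il6 regions, 1 lay in or within 10 kb of the gene.

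Il2, the gene of a T cell growth factor, had 5 of 9 regions lower, and the clearest, 24.4 kb away (chromosome 3, 37150402 to 37160296), fell from 143 ± 5.22 to 50.9 ± 0.141 CPM (-1.49 ± 0.11). Ccl1 (4 of 22), Csf1 (4 of 19), Il9 (3 of 7) and Calca (3 of 7) had lower and no higher regions, except that under cyclic loess Ccl1 had 3 lower and 1 higher. Csf2, the gene of the cytokine GM-CSF, had 3 higher and 2 lower of 24 regions, and under cyclic loess 5 higher and 0 lower. With TMM factors the 2 lower ones lay in or within 10 kb of Csf2 and the 3 higher ones farther away. Its clearest region, 44.4 kb away, rose from 19.8 ± 0.316 to 37.9 ± 0.833 CPM (0.93 ± 0.17). Areg, the gene of the repair factor amphiregulin, had no called region among 10, its smallest p belonging to a region at 5.34 ± 0.810 and 8.60 ± 1.45 CPM (edgeR adjusted p = 0.187). At an unadjusted edgeR p below 0.05 it had 0 regions, and DESeq2 called 0. Arg1, the gene of arginase, had 5 lower of 22 regions (2 under cyclic loess). Its clearest one, 87.4 kb away (-0.97 ± 0.27), lost its call with DESeq2 (-0.98), without PBS replicate 1 (-0.76) and without IL-33 replicate 1 (-0.63).

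**Figure D1:**
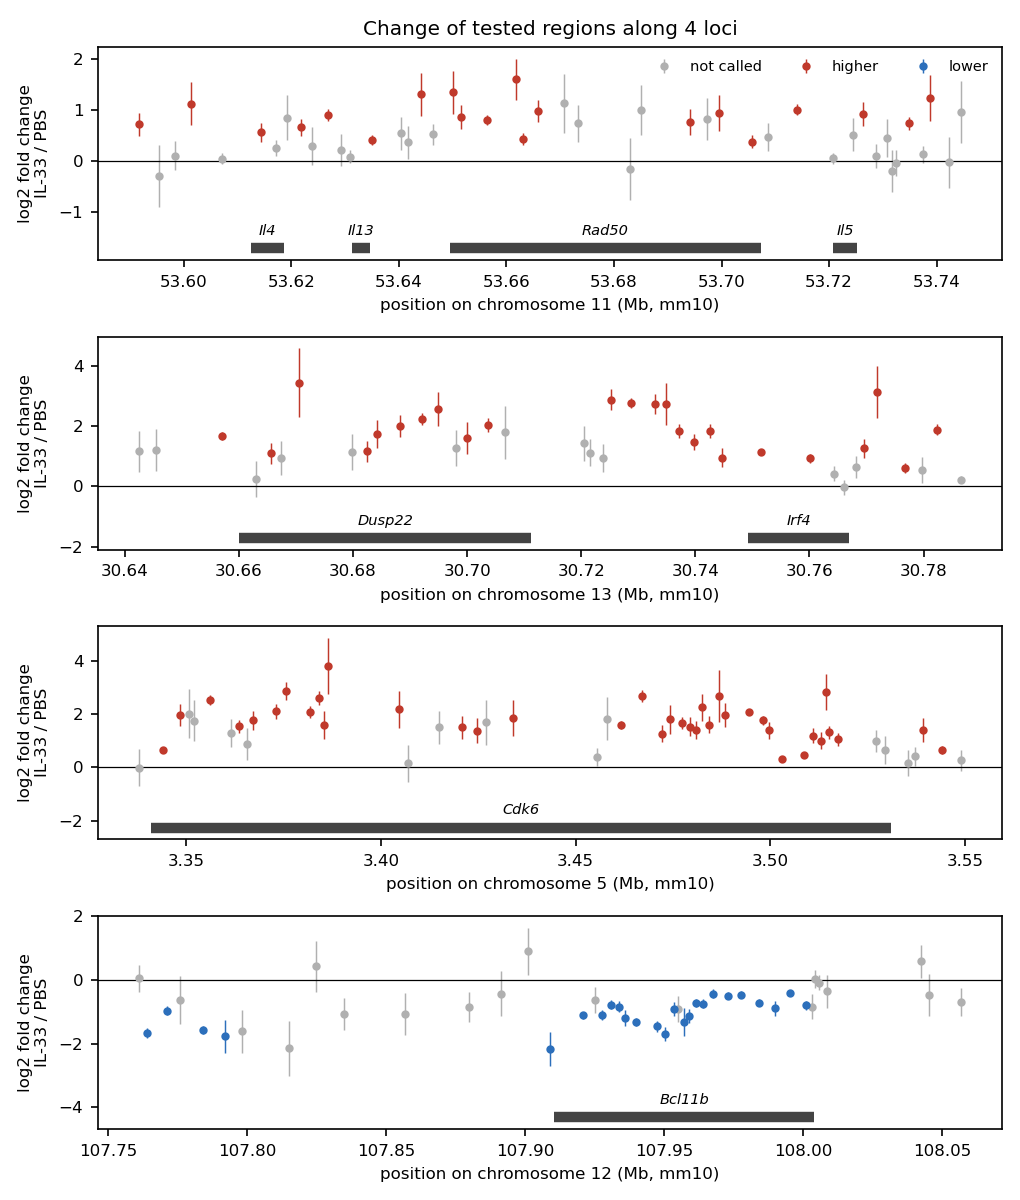
Log2 fold change of Brg1 CUT&Tag counts (IL-33 over PBS, y axis) of each tested region along 4 loci, plotted at the middle of the region (x axis, Mb of the mm10 chromosome). Points are edgeR estimates from 2 libraries per group, bars are standard errors, red and blue mark regions called higher and lower, grey regions were not called, and dark bars are gene spans. Called regions were all higher at the type 2 cytokine locus (20 of 46), around Irf4 and Dusp22 (24 of 39) and at Cdk6 (38 of 53), and all lower around Bcl11b (25 of 44). These 4 windows were not part of the plan fixed beforehand.

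Genes of ILC2 identity factors had many regions and mixed changes, with 101 higher and 182 lower among 1239 (111 and 193 adjusted over the list alone). With total counts 133 were higher and 147 lower, and under cyclic loess 128 and 135. The list was not called (camera adjusted p = 0.251, and 0.292 with an estimated correlation). Its median of -0.07 became 0.03 with total-count scaling. Bcl11b, the gene of a zinc finger factor needed for ILC2 identity, had 33 lower and 0 higher of 72 regions. The clearest lay 124 kb away (chromosome 12, 107781301 to 107786814) and fell from 93.7 ± 2.05 to 31.9 ± 6.45 CPM (-1.56 ± 0.13). Zeb1 had 12 lower and 0 higher of 24 regions. Rora, which encodes a nuclear receptor needed for ILC2 development, had 28 lower and 5 higher of 157 (17 and 8 under cyclic loess), its clearest intragenic region falling from 65.7 ± 8.25 to 26.1 ± 0.0143 CPM (-1.33 ± 0.14). Gata3, the gene of the lineage-defining factor, had 28 lower and 14 higher of 156 regions. The higher ones all lay more than 10 kb from the gene, as did all but 4 of the lower ones. The clearest region was a higher one 895 kb away. The strongest named region of the list, inside Ets1 (chromosome 9, 32709521 to 32721733), fell from 508 ± 2.96 to 313 ± 2.85 CPM (-0.70 ± 0.07), and by less under cyclic loess (-0.29). Over the whole gene 20 of 110 regions were lower and 8 higher, a balance that turned under cyclic loess (14 lower, 16 higher).

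Some identity factors moved the other way. Id2, an inhibitor of helix-loop-helix factors required by all innate lymphoid cells, had 18 higher and 6 lower of 103 regions, the clearest being 205 kb away (1.23 ± 0.13). Of these calls of Id2, 1 higher and 0 lower ones lay in or within 10 kb of the gene. Runx3 had 12 higher and 2 lower of 62 (14 and 0 under cyclic loess), with its clearest region, 43.1 kb away, rising from 36.2 ± 1.20 to 90.6 ± 8.42 CPM. Nfil3 had 8 higher and 1 lower of 23, and Notch1 had 6 higher and 0 lower of 18.

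Receptor genes of ILC2s lost signal more often than they gained it. Of 438 regions 101 were lower and 27 higher (111 and 41 adjusted over the list alone), and under cyclic loess 69 were lower and 42 higher. The list was called downward at the preset correlation (camera adjusted p = 0.0153), with adjusted p = 0.116 with an estimated correlation, 0.199 under cyclic loess, 0.0644 without IL-33 replicate 1 and 0.0840 without Kit. With only regions in or within 10 kb of the gene, camera called the receptor list downward (adjusted p = 0.0029). Il1rl1, the gene of the IL-33 receptor ST2 and a marker of the sort, had 8 lower and 1 higher of 21 regions (5 and 3 under cyclic loess), and an intragenic region (chromosome 1, 40444579 to 40452018) fell from 134 ± 5.88 to 73.7 ± 2.03 CPM (-0.86 ± 0.11). Kit, the stem cell factor receptor gene, had 17 lower and 2 higher of 44 regions. Thy1 had 8 lower of 23, Cd44 had 13 lower and 2 higher of 46, and Icos, a costimulatory receptor gene, had 9 lower and 2 higher of 39. Il9r (3 lower of 6, clearest -0.69 ± 0.12) and Il7r (3 lower of 12) had no higher region. Under cyclic loess Il9r had 1 lower region, and Il7r had 1 lower and 1 higher. The clearest region of Il7r (-0.47 ± 0.14) lost its call under cyclic loess (-0.22), without PBS replicate 2 (-0.39) and without IL-33 replicate 1 (-0.37). Under cyclic loess Il17rb had 1 lower and 1 higher of 6 regions. With TMM factors it had 1 lower region (-0.92 ± 0.34, edgeR adjusted p = 0.0423), a call that ended with any 1 library left out (-1.01 to -0.81) and with DESeq2 (-0.94), total counts (-0.82), no low-count filter, the replicate block or thinned libraries.

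Against this direction, Klrg1, the gene of an inhibitory lectin found on activated ILC2s, had 5 higher and 0 lower of 13 regions. Its clearest one, 6.38 kb away (chromosome 6, 122257621 to 122264215), rose from 56.8 ± 1.57 to 99.3 ± 4.72 CPM (0.81 ± 0.12). Tnfsf4, the gene of OX40 ligand, had 3 higher of 17 regions, all more than 10 kb from the gene, and none lower. At Il2ra, the gene of the CD25 antigen used in the sort, the region with the smallest p lay 18.3 kb away and rose from 8.63 ± 2.32 to 30.4 ± 2.76 CPM (1.82 ± 0.22). Of its 27 regions 3 were higher and 5 lower, and under cyclic loess 4 were higher and 1 lower. With TMM factors the 5 lower ones lay in or within 10 kb of the gene and the 3 higher ones farther away.

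**Figure D2:**
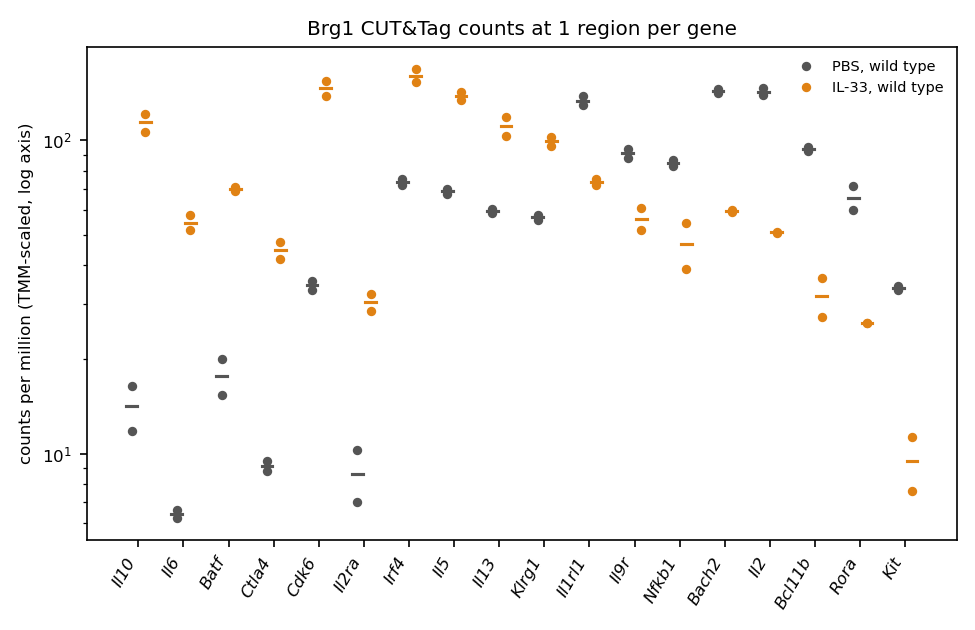
TMM-scaled CPM (y axis, log scale) at 1 region for each of 18 named genes (x axis), the region with the smallest p of that gene. Each point is 1 library, grey for PBS and orange for IL-33, and short lines are means of 2 libraries. For Il10 the means are 14.2 and 114 CPM, and for Il2 they are 143 and 50.9 CPM.

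NF-kB and AP-1 signalling genes changed in both directions, 68 of 648 regions rising and 93 falling (72 and 101 adjusted over the list alone), while 79 rose and 66 fell with total counts and 77 rose and 55 fell under cyclic loess. The list was not called (camera adjusted p = 0.894, and 0.618 with an estimated correlation). Its mean was 0.05, while its median (-0.02) and camera's direction were negative. Among its transcription factor genes, Batf, of the AP-1 family, had 13 higher and 0 lower of 21 regions, the clearest 18.5 kb away (chromosome 12, 85663664 to 85668198), where signal rose from 17.7 ± 3.24 to 70.1 ± 1.35 CPM (1.99 ± 0.15). Irf4 had 11 higher and 0 lower of 14, including the region over its end (chromosome 13, 30746826 to 30756148), which rose from 73.5 ± 2.26 to 161 ± 10.4 CPM (1.13 ± 0.10). Stat5b had 13 of 18 and Stat5a 4 of 12 regions higher and none lower (12 and 2 higher under cyclic loess). Bhlhe40 had 4 higher and 3 lower of 23 regions (8 and 1 under cyclic loess), and its clearest one, 37.2 kb away, rose from 43.2 ± 0.702 to 108 ± 12.3 CPM. Jun had 5 higher and 2 lower of 33. Others had lower regions only: Nfatc1 9 of 49, Egr1 6 of 11, Fosb 6 of 15 and Egr3 3 of 5, although under cyclic loess Fosb had 4 lower and 1 higher.

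Genes of NF-kB subunits and inhibitors had calls in both directions. Nfkb1 had 15 lower and 1 higher of 57 (8 and 1 under cyclic loess), and its clearest intragenic region fell from 84.7 ± 2.84 to 46.7 ± 11.1 CPM (-0.87 ± 0.12). Tnfaip3, the gene of the NF-kB inhibitor called A20, had 19 lower and 0 higher of 70 regions, and under cyclic loess 12 lower and 6 higher. Rel, Rela and Nfkb2 had 1 lower region each and Relb had 2, with none higher, and under cyclic loess the calls of Rel and Rela ended. Nfkbiz had 4 higher and 3 lower of 38, and Nfkbib had 1 higher of 3. Nfkbid had 2 lower of 3 and Nfkbie 1 lower of 4, with none higher, and the call of Nfkbie ended under cyclic loess. Nfkbia, an inhibitor gene of NF-kB, had 1 higher region 21.3 kb away (1.03 ± 0.12) and 1 lower of 20, and under cyclic loess 1 higher and 0 lower. The single region of Junb (chromosome 8, 84978388 to 84986996) was strong in all libraries, at 427 ± 9.42 and 354 ± 54.9 CPM. Its log2 fold change of -0.27 ± 0.08 was called, changed sign under cyclic loess (0.13), and lost its call with DESeq2 (-0.29), the likelihood ratio test, total counts (-0.16), without PBS replicate 1 (-0.24) and without IL-33 replicate 2 (-0.12).

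Negative regulators of lymphocyte activation had 46 higher and 42 lower of 420 regions (51 and 51 adjusted over the list alone), with 62 higher and 35 lower under total-count scaling, 58 and 30 under cyclic loess, and 43 and 51 under RLE scaling. The list was not called (camera adjusted p = 0.945, and 0.897 with an estimated correlation). Among its genes of inhibitory receptors, Ctla4 had 8 of 20 regions higher, Tigit 4 of 12, Havcr2 4 of 10 and Lag3 2 of 4, with none lower, while Cd200r1 had 1 of 8 lower, a call that ended under cyclic loess, and none higher. The clearest Ctla4 region, 8.96 kb away (chromosome 1, 60897802 to 60900069), rose from 9.15 ± 0.491 to 44.7 ± 3.91 CPM (2.29 ± 0.19). Pdcd1, the gene of the receptor PD-1, had 1 of 12 regions higher (5 under cyclic loess). At its end, signal rose from 91.6 ± 8.37 to 125 ± 1.59 CPM (0.44 ± 0.11), a call that ended without PBS replicate 2 (0.36). Dusp4, a MAP kinase phosphatase gene, had 8 of 27 regions higher, all more than 10 kb from the gene. The orphan nuclear receptor gene Nr4a2 had 4 of 8 lower, one of them falling from 111 ± 6.91 to 53.3 ± 2.65 CPM, and Rgs2 had 3 of 9 lower.

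Of 622 regions of quiescence and migration genes, 122 were lower and 39 higher (134 and 41 adjusted over the list alone), and under cyclic loess 98 were lower and 52 higher. Of the 25 genes, 8 had lower regions only, 2 higher only, 12 both and 3 neither. Camera called the list downward (adjusted p = 0.0153), with adjusted p = 0.116 with an estimated correlation. The camera adjusted p was 0.0029 with only regions in or within 10 kb of the gene and 0.0218 under cyclic loess. Bach2, the gene of a repressor that restrains lymphocyte effector programmes, had 34 lower and 3 higher of 95 regions. Its clearest intragenic region (chromosome 4, 32287493 to 32293456) fell from 144 ± 3.13 to 59.4 ± 0.650 CPM (-1.28 ± 0.11). Btg1, an antiproliferative gene, had 23 lower and 2 higher of 77, and Klf4 had 8 lower of 27. Ccr4, a chemokine receptor gene, went the other way with 5 of 10 regions higher (clearest 1.63 ± 0.16). Without Bach2 the list's adjusted p was 0.198.

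Proliferation and metabolism genes gained signal at a few loci. The proliferation list had 47 higher and 14 lower of 236 regions (52 and 17 adjusted over the list alone, camera adjusted p = 0.0153 upward). Under cyclic loess it had 44 higher and 4 lower. Its adjusted p = 0.292 with an estimated correlation, and 0.793 without Cdk6. The camera adjusted p was 0.0029 with only regions in or within 10 kb of the gene and 0.0043 under cyclic loess. Cdk6 held 37 of the 47 higher regions, the clearest of which (chromosome 5, 3493521 to 3495736) rose from 34.5 ± 1.61 to 147 ± 11.2 CPM. All 3 regions of the mitotic kinase gene Cdk1 rose. In 19 of the 30 genes, among them Mki67, Top2a and Ccnb1, no region was called. Cdkn1a, the gene of a cell cycle inhibitor, had 4 of 15 regions lower (2 under cyclic loess, clearest -0.75 ± 0.14). The metabolism list had 58 higher and 24 lower of 428 regions (60 and 27 adjusted over the list alone, camera adjusted p = 0.0153 upward). With total counts it had 76 higher and 14 lower, and under cyclic loess 59 and 14 (camera adjusted p = 0.0193). Its adjusted p = 0.116 with an estimated correlation, 0.0658 without IL-33 replicate 2, 0.323 with only regions in or within 10 kb of the gene, and 0.508 without Myc. Myc, the gene of a growth-promoting transcription factor, held 42 of the higher regions, and 20 of those lay in the neighbouring noncoding gene Pvt1 (chromosome 15, 62037986 to 62260215). Of the 42, 3 lay in or within 10 kb of Myc. Pparg had 6 higher and 1 lower of 49, whereas 10 of the 26 metabolism genes had lower regions only, among them Aldoa, Ldha and Slc7a8. Under cyclic loess Slc7a8 had 2 lower regions, and Aldoa and Ldha had none. With 1 region per gene, the one with the highest mean count, camera called none of the lists of receptors, quiescence and migration, proliferation or metabolism (adjusted p = 0.700 to 0.732). This setting moves the test to strong regions as well as to fewer ones. It thus does not isolate the dependence between regions of 1 gene.

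**Figure D3:**
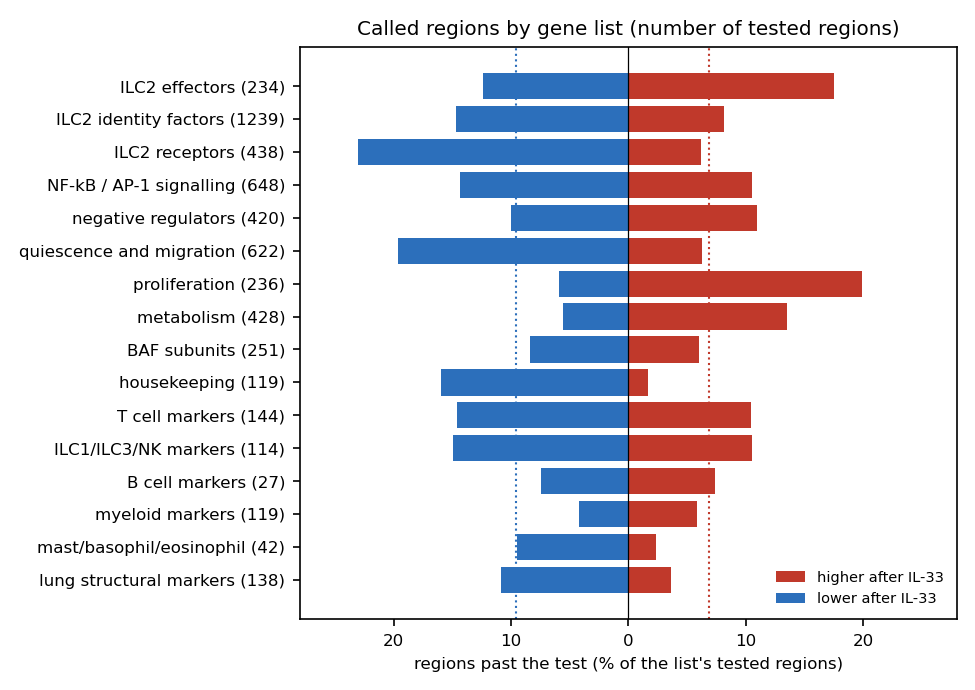
Percent of each gene list's tested regions that were called higher (red, to the right) or lower (blue, to the left) after IL-33, with the number of tested regions in parentheses. Dotted lines mark the shares over all tested regions, 6.86% higher and 9.61% lower, and each bar rests on 2 libraries per group. The receptor list has 101 lower and 27 higher regions, and the proliferation list 14 lower and 47 higher.

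Subunit genes of the BAF complex itself were not called as a list, with 15 higher and 21 lower of 251 regions (15 and 19 adjusted over the list alone), and 16 higher and 15 lower with total counts (camera adjusted p = 0.894, and 0.750 with an estimated correlation). Its mean (0.06) and median (0.01) were positive and camera's direction negative. At Smarca4, which encodes Brg1, 1 of 12 regions was lower, from 26.8 ± 8.77 to 14.9 ± 2.14 CPM (-0.84 ± 0.20). That call ended without PBS replicate 2 (-0.46), and the median log2 fold change of the 12 regions was 0.49. Housekeeping genes had 19 lower and 2 higher of 119 regions (19 and 2 adjusted over the list alone), and 13 lower and 5 higher with total counts and 10 lower and 4 higher under cyclic loess. This list was not called (camera adjusted p = 0.251, and 0.463 with an estimated correlation). Gene-end regions of Eef1a1 (-0.79 ± 0.12; 1 of 7 regions lower), Polr2a (-0.68 ± 0.12; 1 of 5) and Eef2 (-0.72 ± 0.14; 2 of 6, and 1 under cyclic loess) were among the lower ones, and none of these genes had a higher region.

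None of the 6 marker lists of other cell types was called by camera with all libraries, their adjusted p-values ranging from 0.185 to 0.916 at the preset correlation and from 0.463 to 0.894 with an estimated one. Without PBS replicate 2 the list of mast cells, basophils and eosinophils was called downward (adjusted p = 0.0317, over all its alternatives 0.0317 to 0.830). T cell markers had 15 higher and 21 lower of 144 regions (16 and 21 adjusted over the list alone), and 16 higher and 14 lower with total counts. Their median (0.04) and mean (0.11) were positive and camera's direction negative. Ikzf2, the gene of the factor Helios (7 higher, 4 lower of 50), and Cd5 (2 of 8 higher) rose most clearly, while Cd28 had 6 of 14 regions lower. Markers of ILC1s, ILC3s and NK cells had 12 higher and 17 lower of 114 (14 and 18 adjusted over the list alone). Of Ifng 5 of 15 regions were lower, all of them more than 10 kb from the gene. Of Gzmb 3 of 5 regions were higher, 1 of them within 10 kb of the gene. B cell markers had 2 higher and 2 lower of 27, the same adjusted over the list alone. Myeloid markers had 7 higher and 5 lower of 119 (5 and 4). The clearest of these regions, 11.4 kb from Itgam, rose from 2.71 ± 0.725 to 18.2 ± 4.44 CPM. A weak region inside Flt3 rose from 0.275 ± 0.389 to 3.60 ± 0.624 CPM, which DESeq2 did not call. Markers of mast cells, basophils and eosinophils had 1 higher and 4 lower of 42 (1 and 4). The higher one, inside Ccr3, rose from 2.79 ± 2.13 to 19.4 ± 0.180 CPM. Lung structural markers had 5 higher and 15 lower of 138 (5 and 15). The median of that list (0.03) was positive, its mean (-0.10) and camera's direction negative, and its median was -0.09 under cyclic loess. Several of its lower regions lay far from the gene, such as one 185 kb from Pdgfra and one 127 kb from Kdr, both on the stretch of chromosome 5 that also holds Kit.

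The fold change also varied with the abundance of a region. In the eighth of regions with the lowest counts the median log2 fold change exceeded that in the eighth with the highest counts by 0.44 with TMM factors and by 0.44 with total counts. The same difference was -0.11 under cyclic loess. Between replicates it was 0.09 for PBS replicate 1 over 2 and -0.03 for IL-33 replicate 1 over 2.

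**Figure D4:**
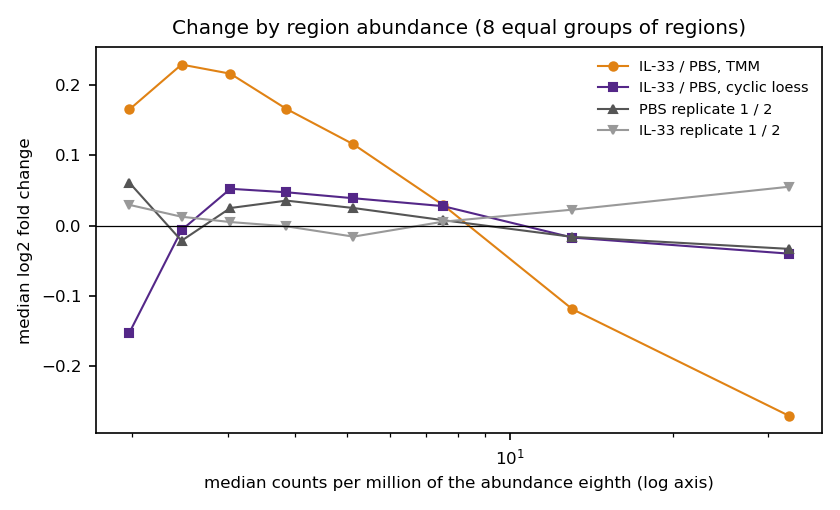
Median log2 fold change (y axis) in 8 equal groups of regions ordered by abundance, against the median CPM of the group (x axis, log scale). Orange circles are IL-33 over PBS with TMM factors, purple squares the same under cyclic loess, and grey triangles compare the 2 replicates of each group. The orange line drops by 0.44 from the weakest to the strongest eighth, and the purple line rises by 0.11.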

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

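The alternatives for gene lists other than total-count scaling, the estimated correlation, 1 region per gene and the replicate block were chosen after the data were seen, as were thinning and, for region classes, all but total counts, cyclic loess and the block. Of 16686 calls, 98.7% were kept in the same direction with RLE scaling, 97.0% with the likelihood ratio test and 92.9% without a low-count filter. The share was 90.5% after thinning to 5846606 counts per library, 85.7% with total counts, 76.0% under cyclic loess and 58.0% with DESeq2. Under cyclic loess 1 call took the opposite direction. DESeq2 called 9676 regions (3770 higher, 5906 lower), an adjusted p below 0.01 left 11026 (4588 and 6438), and a log2 fold change of at least 1 left 9294, of which 4114 were lower, the last pair by construction. Leaving out 1 library gave 10920 to 11643 calls, 4408 to 5085 higher and 5835 to 6936 lower. The lone library was then assumed to vary like the other group, and fewer samples lower the count by construction. The odds ratio of gene ends among lower against higher calls stayed between 1.72 and 5.76 over all alternatives. Of the 104 named regions 102 were called. Over all alternatives but the minimum of 1 on the log2 scale, 13 of them lost their call at least once, and Junb alone reversed, to 0.13 (0.128736) under cyclic loess. The cause was not tested.

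Camera called 4 lists, and 0 with an estimated correlation, 0 with 1 region per gene at either correlation, and 0 without the member with the most called regions. The correlations estimated for the 4 called lists lay between -0.0013 and 0.0099, none above the preset 0.01. The loss of their calls with the estimate thus did not come from a higher correlation used in the test. The estimate rests on differences between replicates, with few residual degrees of freedom. It therefore cannot show whether regions of a gene changed independently between groups. Neighbouring regions changed together, as described below. Lists that camera called in neither setting but whose direction changed had the following adjusted p-values. They were 0.709 (0.709307) for T cell and lung structural markers with 1 region per gene and 0.830 (0.830128) when its correlation was estimated. Metabolism, called with all regions, reversed in the same settings at 0.709 and 0.849. With regions within 10 kb they were 0.323 for negative regulators and 0.562 for lung structural markers, and under cyclic loess 0.630 for NF-kB and AP-1 genes and 0.932 for T cell markers. Without the top member they were 0.832 for effectors, NF-kB and AP-1 genes and BAF subunits, and 0.793 for negative regulators. With 1 library left out, adjusted p ranged from 0.714 to 0.998 for BAF subunits, from 0.918 to 0.998 for negative regulators and from 0.703 to 0.961 for T cell markers. The cause of these reversals was not tested.

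Same-numbered libraries did not deviate together (correlation across regions -0.02). No shared effect of the replicate number was thus seen, which does not exclude that libraries were prepared in pairs. With the replicate block, 15486 regions were called, of which 6533 were higher and 8953 lower. The block changed no list's call, and of the named regions it ended the call of Il17rb alone. How much depth limits the calls at weak regions was not tested, beyond the calls kept after thinning. Not run were the comparisons with the knockout libraries, the fit of all 3 groups and the restriction to regions above the knockout signal, since those libraries were not analysed here.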

Other observations

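Many of the loci with the most calls in 1 direction lay outside the fixed lists, and were chosen after their values were seen. Etv6, the gene of an ETS-family repressor, had 28 higher and 0 lower of 73 regions with a median log2 fold change of 0.87. Sgms1, a gene of sphingomyelin synthesis, had 31 higher of 93, and the RNA-binding protein gene Msi2 had 24 of 59. Vmp1, an autophagy gene, had 21 of 31 regions higher and Trerf1 had 24 of 48, and Adgrg1, the gene of an adhesion receptor, had 18 of 21. Cd83, the gene of a lymphocyte and dendritic cell activation marker, had 17 of 33 higher, most of them more than 10 kb away. None of these genes had a lower region, and all had 13 or more higher regions under cyclic loess.

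In the other direction, Atp2b1, a plasma membrane calcium pump gene, had 35 lower and 0 higher of 72 regions (median -0.79). Sema6d, a semaphorin gene, had 27 of 40 (-1.53), Chn2 23 of 62, Susd6 21 of 34 and Mdfic 20 of 30. Ptger4, the gene of a prostaglandin E receptor, had 18 lower of 43 regions, reaching up to 525 kb from the gene. None of these had a higher region except Atp2b1 with 1 under cyclic loess. The region with the most counts, chromosome 17 from 39843144 to 39846754, held 0.0609% to 0.0705% of each library's counts, so that no single region dominated a library.

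The tests of the X chromosome below were chosen only after the result was seen, and those of abundance and neighbouring regions before their own values were seen.

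Strong regions fell and weak regions rose, with a gap of 0.44 in median log2 fold change between the weakest and strongest eighths. A difference in depth was predicted to shrink this gap after thinning all libraries to the same total, and it stayed at 0.435412. Thinning lowers all regions of a library by the same expected factor, so it could test little beyond counting noise. An effect of depth on which reads or regions were counted stays open. A more uniform background in the IL-33 libraries stays open too. At fixed counts per bp the fold change did not follow region width (partial Spearman correlation across regions -0.0399301), whereas at fixed width it followed counts per bp (-0.20), which is the pattern such a background would give and is also what redistribution of Brg1 from strong to weak regions might give. The trend is not the whole cause of the calls, since 76.0398% of them kept their direction and call under cyclic loess.

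Neighbouring regions changed together. Of pairs of called regions 2 to 10 kb apart 94.9% had the same direction, at 10 to 50 kb 85.6%, and at 200 to 1000 kb 54.6%, against 51.4% by chance. A technical bias of whole stretches of chromosome between libraries would also appear between replicates. The covariance of replicate differences at 10 to 50 kb was only 0.017913 of that of the group difference, which argues against such a bias arising in single libraries. A bias shared by both libraries of a group was not tested, and no batch is given in the labels. No biological explanation of this pattern was tested.

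Regions on the X chromosome were lower after IL-33. Their median log2 fold change was -0.39, while chromosome medians of autosomes ranged from -0.04 to 0.13, and 182 of 1181 X regions were called lower and 36 higher. The X held 1.02% ± 0.0275 (SD, n = 2) of counts in PBS and 0.837% ± 0.0198 in IL-33 libraries, and its shift against autosomes lay between -0.46 and -0.36 over all alternatives. By abundance eighth it ranged from -0.54 to -0.19 and was smallest in the strongest regions. The mix of region classes and abundance on the X argues against being the cause, since against autosomal regions of the same class and abundance the median difference was -0.358221. Male mice among the IL-33 pools would lower the X, and the labels state females. The only region on the Y gave 3 and 8 counts in PBS libraries and 1 count in the IL-33 libraries together, which runs against it, but 1 region near the floor is too little to decide. A difference between library preparations cannot be told apart from treatment without batch labels, although replicates differed by only 0.20939 of the group difference in X share, and a change of the X chromosome with IL-33 stays an untested hypothesis.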
